A study of Gallus gallus with 6 samples.

How the data were processed

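RNA from chicken (Gallus gallus) basilar papillas was sequenced in 6 libraries, 3 infected with RCAS(A) and 3 with RCAS(A)-Wnt9a, each from a pool of 24 papillas. Per the labels' protocols, otocysts were infected on embryonic day 3 and papillas taken on embryonic day 6, total RNA was extracted with an on-column DNase step, and a stranded Illumina kit made the libraries. Groups and replicate numbers came from the sample titles, which number the RCAS(A) pools 2, 3 and 4 and the RCAS(A)-Wnt9a pools 1, 2 and 3.

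The submitters' processing notes name TopHat2, DESeq, edgeR, DESeq2 and the galGal4 build. The counting tool, its strand setting and the annotation release are not given in the sources used here, so overlapping and antisense genes cannot be told apart from their partners, and reads of near-identical paralogs may be split. The authors deposited whole-number counts per Ensembl gene for each library, with totals of 19200235 to 23017150. The authors' DESeq2 table holds, per the file headers, a mean normalized signal (baseMean), log2 fold changes with their SE, a Wald score and p-values, and lists only adjusted p under 0.05. The authors' edgeR table holds log2 fold changes, average log2 CPM and p-values, per the file headers, which stand 1 column to the left of their values. The deposited FPKM table gives 1 pooled FPKM per group with confidence bounds, so it was used for signs, gene positions as listed and implied lengths and not for tests.

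Genes kept by edgeR's filterByExpr (12133 of 15955, of which 1443 had no count in any library) were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest, two-sided, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. CPM values are TMM-scaled, and the SE of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 8.06%. With 3 against 3 libraries an exact permutation test of a single gene cannot go below 0.1, so calls rest on the model fitted across genes. In counts simulated for this comparison with 12133 genes, of which 200 were changed, the fit called 12% of genes changed 1.2-fold, 80% at 1.5-fold, 96% at 2-fold and 100% at 4-fold in the right direction, and 15 of its 159 calls were unchanged genes, a larger share than the nominal threshold.

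Symbols were taken from the authors' tables, where 492 of 522 genes have a name, and matched to RefSeq symbols of the GRCg7b assembly for names only (148 by RefSeq accession, 324 by symbol, 2 by description and 18 kept as the authors wrote them). The remaining genes of the count table carry an Ensembl identifier and were tested without a symbol. The named genes follow a rule set before the data were examined. It takes WNT9A, then the 10 largest rises and 10 largest falls among genes with a symbol, adjusted p under 0.05, average log2 CPM of at least 1 and no overlap between the groups' libraries. From each of 22 fixed lists it takes up to 4 members with the smallest p among those past the threshold, or up to 2 as values only where there is none. No symbol stood on more than 1 row.

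Lists were tested with limma 3.58.1 (camera with a preset correlation of 0.01 or an estimated one, and fry) where at least 3 members had a name, which left 12 lists. As all of these members come from the authors' tables of changed genes, the set tests are void as evidence on a list, and only their number of calls is given. Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom, edgeR's exact test, DESeq2 size factors, library size alone, every gene with at least 1 count, a CPM of at least 2 in at least 3 libraries, a replicate block, leaving out each library in turn and a 1.5-fold criterion. A fit with the trend of implied transcript length removed, DESeq2 with a prior on the fold changes and Fisher's exact test of list directions were chosen after the data were seen. Tables were made with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1. Read-level steps and sequence-based checks such as GC content were not analysed here.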

Results

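Basilar papillas, the auditory sensory organs of the chicken inner ear, were profiled by RNA sequencing on embryonic day 6. Right otocysts had been infected on embryonic day 3 with RCAS(A), the parent replication-competent avian retrovirus, or with RCAS(A)-Wnt9a, the same virus carrying Wnt9a. Each group held 3 biological replicates, and each replicate was a pool of RNA from 24 papillas. The count table gave between 19200235 and 23017150 counts per library, and 12133 of its 15955 genes had enough counts to be tested. Within a group, pairs of libraries correlated across genes at r = 0.992 to 0.996 on log2 CPM, and no pair of replicates agreed within counting noise. The first principal component took 34.3% of the variance and separated the groups.

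The series asks which genes act downstream of Wnt9a. WNT9A (ENSGALG00000005401, chromosome 2, 2573611 to 2624503 in galGal4 as listed in the files), which encodes a secreted Wnt ligand, was measured first because the virus carries it. Its level was 8.36 ± 1.77 CPM (SD, n = 3) in the RCAS(A) pools and 769 ± 498 CPM (SD, n = 3) in the RCAS(A)-Wnt9a pools. The RCAS(A)-Wnt9a libraries held 1340, 539 and 427 CPM in replicates 1, 2 and 3, against 7.90, 6.87 and 10.3 CPM in RCAS(A) replicates 2, 3 and 4. The log2 fold change was 6.53 with an SE of 0.70, or 92.3-fold (edgeR quasi-likelihood test, adjusted p = 0.0307). Counts at this gene do not separate viral from endogenous transcripts. The adjusted p rose to 0.164, 0.152 or 0.162 without RCAS(A) replicate 2, 3 or 4 and to 0.0828 without RCAS(A)-Wnt9a replicate 2, while the log2 fold change stayed between 5.86 and 6.82.

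In all, 276 genes changed, of which 174 were higher and 102 lower with RCAS(A)-Wnt9a (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most changes were small: the median absolute log2 fold change of these genes was 0.53, and 28 were at least 2-fold higher and 21 at least 2-fold lower. In all 276 the 3 libraries of one group lay outside the range of the other, a separation that chance gives 10% of genes and that 19.0% of all tested genes showed. A symbol was at hand for 265 of the 276. The count fell to 148 without RCAS(A) replicate 2 and to 146 without RCAS(A) replicate 4, and a criterion of at least 1.5-fold left 116. It was 435 with DESeq2 and 502 with edgeR's exact test.

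Among genes with a symbol, an average log2 CPM of at least 1 and separated libraries, the largest rises apart from WNT9A were in MSX1, SLC16A12, HCN4, SLC24A4, TCF7, FGF3, PRPS2, HTR3A and FGF19. MSX1, a homeobox transcription factor, went from 5.40 ± 0.44 to 24.6 ± 8.85 CPM (SD, n = 3 per group), a log2 fold change of 2.19 (SE 0.27, edgeR adjusted p = 0.00507). FGF3 (ENSGALG00000026853), a fibroblast growth factor, had the smallest p of these genes. It rose from 22.3 ± 0.67 to 71.4 ± 4.99 CPM, a log2 fold change of 1.68 (SE 0.08, edgeR adjusted p = 9.94e-08). FGF19, another growth factor of that family, rose by 1.49 on the log2 scale. HCN4, a hyperpolarization-activated cation channel, rose by 1.78 and SLC24A4, a sodium, calcium and potassium exchanger, by 1.72. PRPS2, which makes phosphoribosyl pyrophosphate, rose by 1.61. SLC16A12, of the monocarboxylate transporter family, rose by 1.91, and HTR3A, a serotonin receptor subunit, by 1.59.

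By the same criteria of symbol, expression and separated libraries, TECTB (ENSGALG00000008802, chromosome 6, 26215253 to 26223330), which encodes beta-tectorin of the tectorial membrane, fell furthest. It went from 48.8 ± 8.63 to 2.78 ± 1.83 CPM (SD, n = 3 per group), a log2 fold change of -4.14 (SE 0.48, edgeR adjusted p = 0.0232). SPARCL1, a matricellular protein gene, had a log2 fold change of -2.62, and RSPO3, an R-spondin that amplifies Wnt signalling, one of -1.88. The others among the 10 largest falls under these criteria were ALPK2 (log2 fold change -1.40), the potassium channel gene KCNJ15 (-1.38), the myosin gene MYO1H (-1.34), IL16 (-1.32), the chloride channel gene CFTR (-1.29), DLK1 (-1.29) and the Wnt receptor gene FZD10 (-1.16). Of the 58 named genes past the threshold, 33 stayed past it in all 6 fits that left out 1 library. Those that did not included TECTB, whose highest adjusted p was 0.110, and FGF19, MSX1, FZD10, SLC16A12 and MYO1H, with highest adjusted p of 0.0824, 0.0618, 0.0729, 0.195 and 0.158. Among the named list members, ARHGEF3, ATP2B2, BDNF, CHRDL1, CIB2, GPC3, HES5, NRP2, RAC3, RHOU, STRA6 and TGFBI also missed the threshold without at least 1 library, with highest adjusted p of 0.0525 (CHRDL1, without RCAS(A)-Wnt9a replicate 2) to 0.184 (RHOU). None of the 58 changed sign in these fits, which was close to fixed in advance because their libraries did not overlap between the groups.

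**Figure D1:**
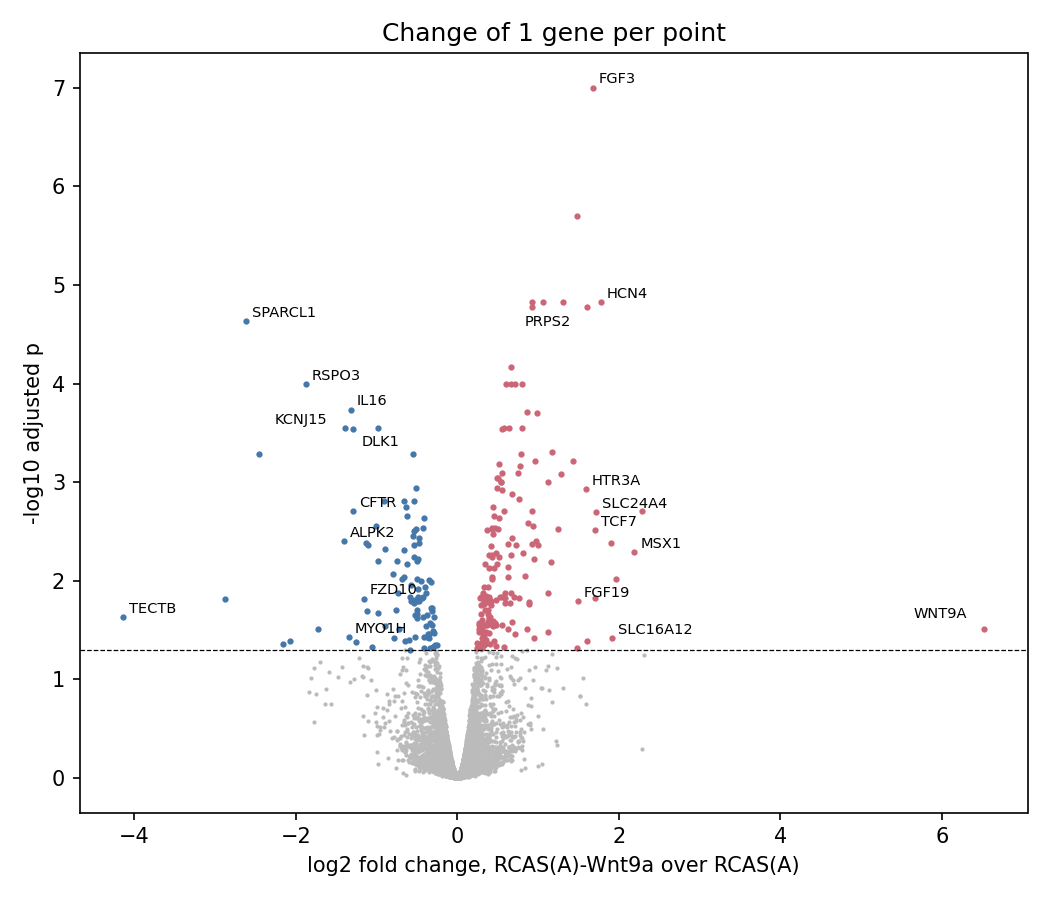
Each point is 1 of the 12133 tested genes, with the log2 fold change of RCAS(A)-Wnt9a over RCAS(A) on the x axis and -log10 of the adjusted p (edgeR) on the y axis. Red points are the 174 genes that were higher, blue points the 102 that were lower, and the dashed line marks an adjusted p of 0.05.

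Gene groups were read through 22 lists fixed in advance. A symbol could be paired with a measured gene only where the authors' deposited tables gave a name, that is, for genes those tables call changed. Only 100 of the 881 list genes therefore have a value here, of which 38 rose, 20 fell and 42 missed the threshold. These members were chosen on these libraries, so their counts are not independent evidence of a list's direction. For the same reason, nearly all named members passed when adjusted over the list alone (99 of 100 distinct genes), and a list with few named members is not shown to be unchanged. Set tests of these members, against other genes (camera) or against no change (fry), are void for the same reason and are not read as results. Only 11 of the 276 changed genes had no symbol, so nearly all list genes without a name were not called or not tested here. Shares of named members are therefore not shares of a list. Among all changed genes with a symbol, 169 rose and 96 fell. By Fisher's exact test of direction against the other changed genes, 0 of 10 lists differed, several too small to pass at any split.

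Canonical Wnt targets and feedback regulators rose in 7 of 13 named members, 1 fell and 5 missed the threshold. NOTUM, a secreted enzyme that inactivates Wnt proteins, rose from 23.4 ± 0.35 to 65.4 ± 7.94 CPM (SD, n = 3 per group; log2 fold change 1.49, SE 0.09, edgeR adjusted p = 2.01e-06). TCF7 and LEF1, transcription factors of the beta-catenin pathway, rose by 1.70 and 0.50 on the log2 scale, ZNRF3, a ubiquitin ligase acting on Wnt receptors, by 0.67 and the feedback inhibitor NKD1 by 0.49.

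Wnt ligands, R-spondins and receptors moved both ways: of 7 named members, WNT9A and the receptor gene FZD4 rose, RSPO3, RSPO2 and FZD10 fell, and 2 missed the threshold. FZD4 went from 197 ± 18.7 to 339 ± 37.4 CPM (SD, n = 3 per group), and FZD10 from 83.9 ± 2.70 to 37.6 ± 9.01 CPM. RSPO2 had a log2 fold change of -0.49. The call of RSPO2 was lost without any single control library, without RCAS(A)-Wnt9a replicate 1 and without replicate 2, where its adjusted p reached 0.107.

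**Figure D2:**
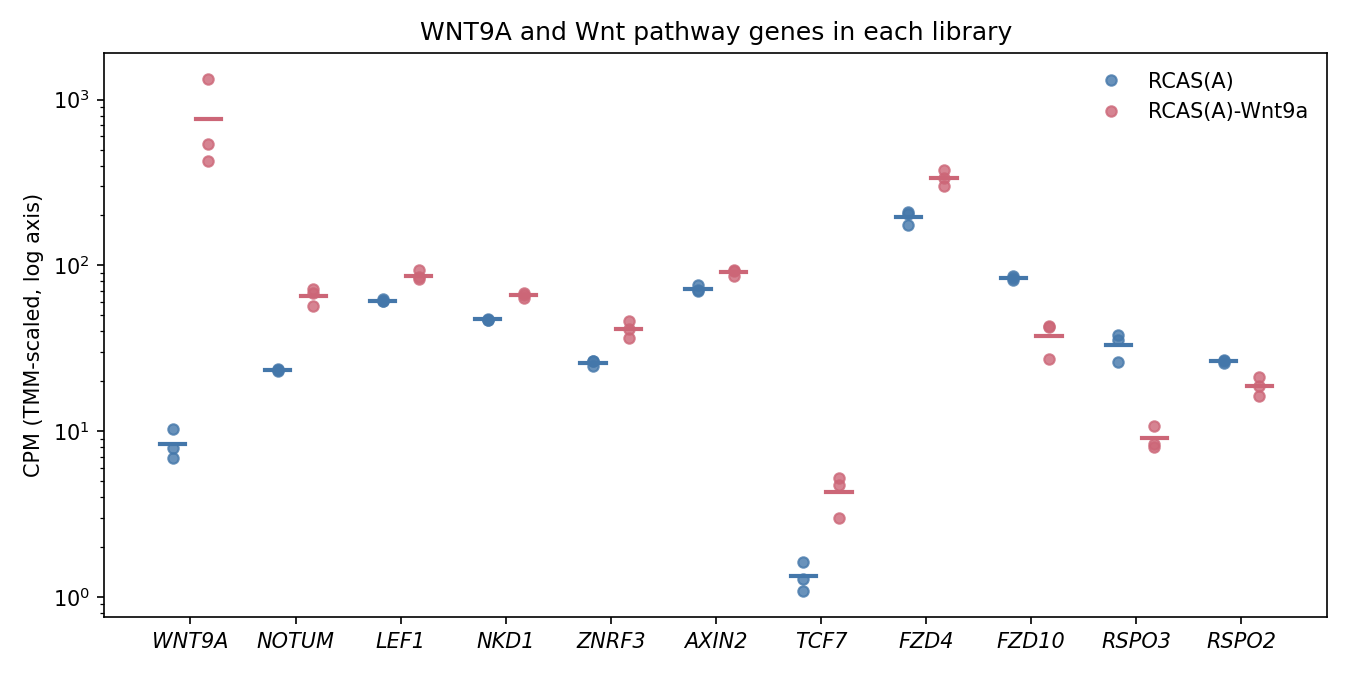
CPM (TMM-scaled, log axis) of WNT9A and 10 other Wnt pathway genes, with 1 point per library, 3 libraries per group and a bar at each group mean. The RCAS(A)-Wnt9a libraries lie above the RCAS(A) libraries for WNT9A, NOTUM, LEF1, NKD1, ZNRF3, AXIN2, TCF7 and FZD4 and below them for FZD10, RSPO3 and RSPO2. The genes were picked for display. AXIN2 is outside the naming rule, and SFRP2, the member of the Wnt target list that fell, is not shown.

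Among prosensory and otic epithelium regulators, 7 of 16 named members rose, 3 fell and 6 missed the threshold. Besides FGF3, FGF19 and MSX1, the homeobox genes DLX5 and LMX1A rose, by 1.12 and 0.77 on the log2 scale. ISL1, a LIM homeobox gene, went from 146 ± 10.1 to 103 ± 10.1 CPM (SD, n = 3 per group; log2 fold change -0.51, edgeR adjusted p = 0.0030). Of the 53 genes in the hair cell list only 4 were named, and 3 of these fell. They were ATP2B2, a plasma membrane calcium pump (log2 fold change -0.45), CIB2, of the mechanotransduction complex (-0.60), and the neurotrophin gene BDNF (-0.74). The fourth, PCDH15, a tip link protein gene, had a log2 fold change of 0.54, with all RCAS(A)-Wnt9a libraries above the RCAS(A) ones, and missed the threshold (adjusted p = 0.0702). BDNF was also the single named member of the neurotrophic list.

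Supporting and nonsensory cell genes included 1 member that rose, 3 that fell and 5 that missed the threshold. TECTB, SPARCL1 and HES5, a Notch effector (log2 fold change -0.78), fell, and ZPLD1 rose by 0.94 on the log2 scale. In the Notch list, DLK1 and HES5 fell and the third named member missed the threshold. Both named FGF pathway members, FGF3 and FGF19, rose.

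BMP and TGF-beta pathway genes rose in 5 of 8 named members, none fell and 3 missed the threshold. SMAD6, an inhibitory SMAD, rose by 0.50 on the log2 scale, CHRDL1, a secreted BMP antagonist, by 0.35, TGFBI by 0.41 and MSX1 by 2.19. Retinoic acid and hedgehog genes rose in 3 of 6 named members: the retinoid receptor gene RXRG (0.96 on the log2 scale), the retinol transporter gene STRA6 (0.44) and the hedgehog co-receptor gene BOC (0.34). The other 3 missed the threshold, with log2 fold changes of 1.53 for ALDH1A3, -0.38 for RDH10 and -0.48 for CYP26C1 (edgeR adjusted p = 0.149, 0.0544 and 0.226).

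Axon guidance genes had 2 falling members among 4 named. SEMA3D, a secreted semaphorin, went from 82.0 ± 12.5 to 40.9 ± 5.0 CPM (SD, n = 3 per group; log2 fold change -1.003, edgeR adjusted p = 0.00279), and NRP2, a semaphorin receptor gene, had a log2 fold change of -0.48. NTN4 and SLIT2 missed the threshold, with log2 fold changes of -1.22 and 0.22. Actin and microtubule remodelling genes rose in 4 of 5 named members: the kinase gene PAK3 by 0.47 on the log2 scale, the small GTPase genes RAC3 and RHOU by 0.60 and 0.30, and the exchange factor gene ARHGEF3 by 0.35. SHROOM3, with a log2 fold change of 0.25, missed the threshold. Extracellular matrix and adhesion genes included 4 that rose, 2 that fell and 5 that missed the threshold. LAMA3, a laminin chain, rose by 1.44 on the log2 scale, CHL1, an adhesion molecule of the L1 family, by 0.86 and the glypican gene GPC3 by 0.43, while ITGA8, an integrin chain, had a log2 fold change of -0.91.

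Markers of other cell types that a dissection could hold had few named members. In the periotic mesenchyme list, PRRX1 and HAPLN1 rose by 0.99 and 0.49 on the log2 scale, LUM had a log2 fold change of -0.52, and 8 members missed the threshold, 7 of them with a positive and 1 with a negative log2 fold change. The call of LUM was lost without any single control library and without RCAS(A)-Wnt9a replicate 2 or 3, where its adjusted p reached 0.177. NTRK2, a neurotrophin receptor of the ganglion neuron list, fell by 0.49 on the log2 scale. CDH19 of the glia and neural crest list, FLT1 of the endothelium list, TFRC of the blood list and CTGF of the stress list rose by 0.58, 0.39, 0.24 and 0.40. Each of those 4 rises was lost without at least 3 of the 6 libraries in turn, with highest adjusted p of 0.181, 0.164, 0.171 and 0.124. CELSR1 of the planar cell polarity list, KIF11 of the cell cycle list and TRIM25 of the interferon list were the single named members of theirs. Their log2 fold changes were 0.28, 0.20 and -0.46, with edgeR adjusted p of 0.103, 0.124 and 0.0615.

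**Figure D3:**
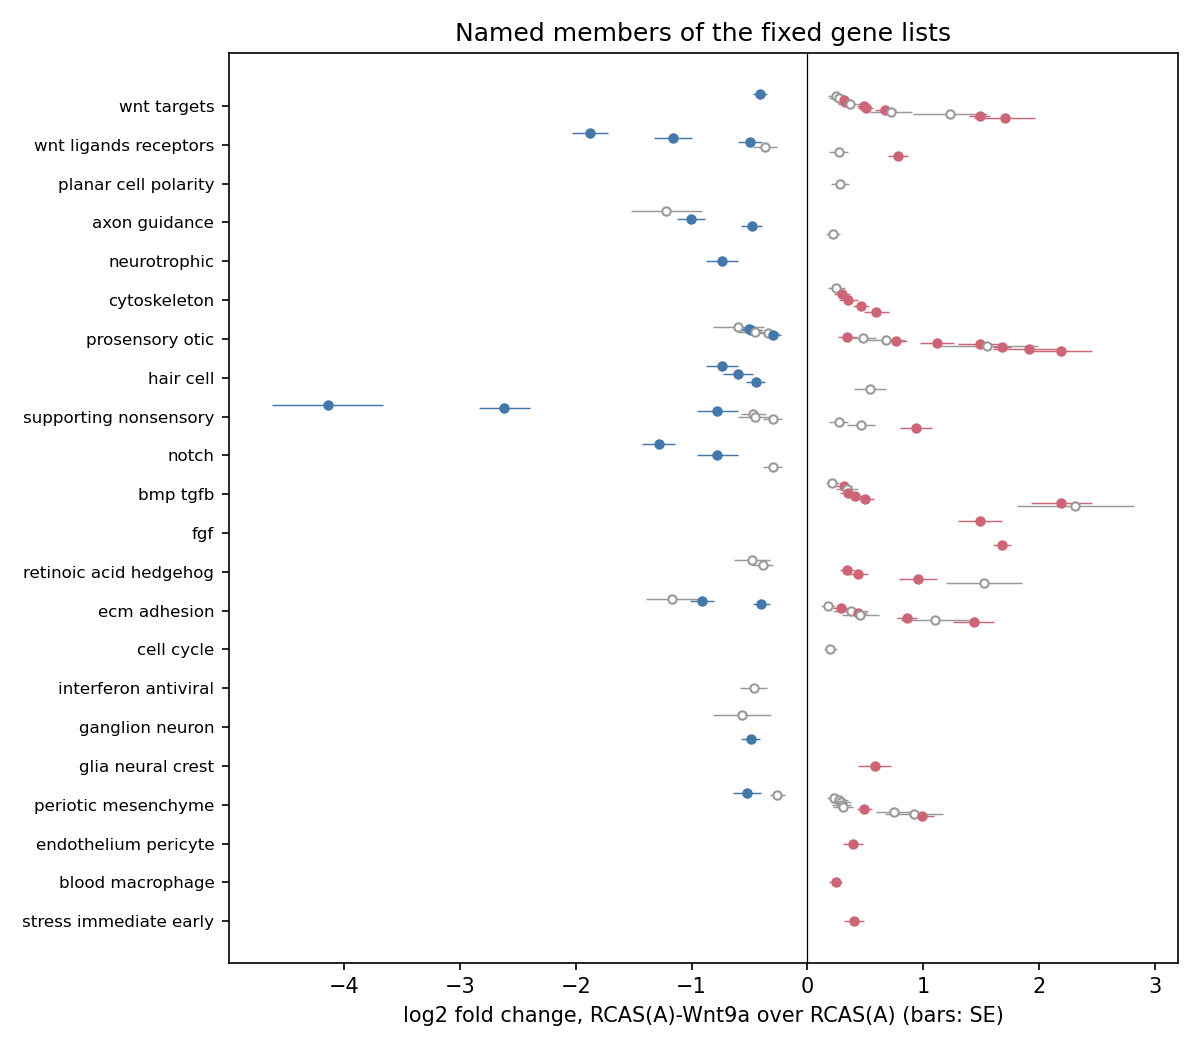
Log2 fold change of RCAS(A)-Wnt9a over RCAS(A) (x axis, bars show the SE) of the named members of each of the 22 lists, WNT9A left out, with 3 libraries per group. Red and blue points are members that rose and fell, and open grey points missed the threshold; the falls of TECTB and SPARCL1 lie furthest to the left.

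The authors' deposited tables hold 500 genes from edgeR and 437 from DESeq2, 415 of them in both. All 276 genes called here were in the authors' deposited table from edgeR and 268 in that from DESeq2, with the same sign in each case. For WNT9A, the authors' deposited table from edgeR gives a log2 fold change of 6.52 and that from DESeq2 only 0.41, and for TECTB they give -4.13 and -0.26. The authors' deposited table from DESeq2 had a median ratio of 0.821 to the log2 fold changes fitted here, with a range of 0.0625 to 0.955 over its 437 genes, lowest for TECTB. The authors' pooled FPKM of WNT9A was 7.13 for RCAS(A) and 953 for RCAS(A)-Wnt9a, and the pooled FPKM moved in the direction of the counts for 272 of 272 changed genes listed. All of these values come from the same libraries, so the shared signs are not independent support.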

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

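The length, prior and Fisher tests were chosen after the data were seen, and causes were not tested unless stated. All 276 changed genes kept their direction in every fit that tested them. That was close to fixed in advance, because their libraries did not overlap between the groups. The number of changed genes was within 1.5 times of 276 with limma-voom, the other scalings, both filters and the length trend removed (252 to 313), but was 435 with DESeq2, 502 with edgeR's exact test, 439 with DESeq2 and a prior, and 116 with the 1.5-fold criterion. Leaving out 1 library gave 146 to 294 genes, lowest without RCAS(A) replicates 4 and 2. List genes past the threshold went from 58 to 93 with DESeq2, prior or not, and 96 with the exact test. Both were nearly fixed in advance, as the authors' calls named these genes. With 1 library left out, 31 to 64 list genes and 35 to 52 named genes (58 in all) passed. For WNT9A the log2 fold change was 5.86 to 6.82 with 1 library left out, and it missed the threshold without any single control (6.49, 6.40 and 6.70) and without RCAS(A)-Wnt9a replicate 2 (6.73). Outside the block fit its adjusted p lay between 5.08e-51 (exact test) and 0.164. With a prior on the fold changes DESeq2 gave WNT9A a log2 fold change of 0.41, against 0.41 in the authors' deposited table. Over the 437 genes of that table this fit differed from it by at most 0.0225, so the prior accounts for the small fold changes there.

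Of 12 lists, camera called 11, 6 with an estimated correlation, and fry 11, while the Fisher test of direction called 0 of 10, several too small to pass at any split. As the authors' calls named the members, these set tests are void as evidence on a list. Of the authors' genes with adjusted p under 0.01, 270 (edgeR) and 242 (DESeq2) were called here. Limma on FPKM with either pseudocount or without a filter was not run, because the FPKM table has 1 pooled value per group. The title numbers share only 2 and 3, and the deviations of same-numbered libraries correlated at -0.01 and 0.19. These few pairs cannot decide whether the numbers pair the pools. The replicate block fit compared only replicates 2 and 3 of each group, as the others had no partner. It called 537 genes, gave WNT9A a log2 fold change of 6.03, and moved 4 other named genes out and 2 in.

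Log2 fold changes rose with transcript length (Spearman rho 0.189 across 11740 genes, not independent replicates), with medians of -0.06 in the shortest 10% and 0.05 in the longest 10%. By mean log2 CPM per group the absolute rho was 0.193 for the real split and 0.202 for another, so the trend is not particular to the virus contrast. Without it 277 genes were called, 251 shared. The 14 named ribosomal protein genes, named only because the authors' tables call them changed, had negative log2 fold changes, with a median of -0.28 that became -0.18, and 2 of them passed before and 0 after. At this depth 12% of simulated 1.2-fold changes were called.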

Other observations

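The tests of splits, neighbouring genes, cell shares and virus dose in this part were chosen after the results, or part of them, were seen. Several genes outside the naming rule, chosen after their values were seen, are list members already counted in the groups described above. The transcription factor genes DLX3 and PAX2 rose by 1.91 and 0.34 on the log2 scale, as did the Wnt target AXIN2 by 0.33 and the BMP ligand gene BMP7 by 0.32 (edgeR adjusted p = 0.00411, 0.0439, 0.0148 and 0.0345). SOX2, a prosensory transcription factor gene, went from 70.3 to 50.3 mean CPM (log2 fold change -0.49, adjusted p = 0.0122), and SFRP2, a secreted Wnt modulator, from 134 to 100.3 mean CPM (-0.41, adjusted p = 0.00231). ALDH1A3, a retinoic acid synthesis enzyme, had a log2 fold change of 1.53 that missed the threshold (adjusted p = 0.149), as did MSX2 with 2.31 (adjusted p = 0.0567). DLX3 and MSX2 had low counts, with mean CPM of 0.66 and 0.57 in RCAS(A) and 2.48 and 2.85 in RCAS(A)-Wnt9a.

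Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes as the real one, which was the real split itself, with 276 genes against at most 1 in the others. With 10 splits no share under 0.05 is possible.

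Changed genes lay beside each other on the chromosomes: among 11977 tested genes with a position, 21 adjacent pairs changed in the same direction and 2 in opposite directions, against a mean of 3.24 and a maximum of 10 same-direction pairs in 1000 permutations within 20 bins of expression (permutation p = 0.001, the smallest they can give). The pairs included FGF19 with FGF3 on chromosome 5 (48.8 kb apart), LRRC45 with NOTUM on chromosome 18 (46.1 kb), STX18 with MSX1 on chromosome 4 (154.6 kb), CHL1 with CNTN6 on chromosome 12 (256.1 kb) and, among falling genes, PIWIL1 with FZD10 on chromosome 15 (67.8 kb) and BEGAIN with DLK1 on chromosome 5 (128.9 kb). There were 13 pairs over 10 kb apart, where permutations gave at most 9, and by their distance these genes do not overlap as listed. Read-through transcripts would also raise the count above the permutations, so this count cannot decide on them. Overlap and read-through remain open for the 8 pairs up to 10 kb apart, such as RXRG with LMX1A at 4.57 kb, and read-through for the others. A bias of the whole region is argued against, as the 20 nearest tested genes had a median signed log2 fold change of 0.012 (95% bootstrap interval 0.0029 to 0.040) against 0.88 in the pairs. GC content of single genes was not analysed here, and a candidate explanation that stays open is regulation shared by neighbouring genes.

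Falling prosensory, hair cell and supporting cell genes could come from a lower share of papilla epithelium in the RCAS(A)-Wnt9a pools, with more of every other cell type. Over 16 named markers of other cell types, 5 rose, 2 fell and the log2 fold changes spread from -0.56 to 0.99, with a Cochran's Q of 283.9 on 15 degrees of freedom against a common shift. However, only 16 of 174 listed markers (9.20%, below the 80% needed) have a name, all from genes the authors' tables call changed, so this check is void and cell shares cannot be told apart from changes within cells. Of the 11 named mesenchyme markers, 9 had positive log2 fold changes and 2, LUM and COL5A2, negative ones. Among the abundant collagen genes of that list, none of which passed the threshold, the log2 fold change was 0.29 for COL1A2 (497 to 607 mean CPM), 0.27 for COL5A1 (254 to 307 mean CPM) and -0.26 for COL5A2 (689 to 576 mean CPM).

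RCAS(A)-Wnt9a replicate 1 held the most WNT9A, and it was also the most extreme library in many falling genes. Among genes called without it, it lay beyond both other RCAS(A)-Wnt9a libraries in 53.4% of 103 falling genes (exact 95% interval 43.3% to 63.3%) and in 29.5% of 176 rising genes (22.9% to 36.9%). Both intervals treat genes as independent, although genes of 1 pool can move together, and are then too narrow. The genes were called on the other libraries, which favours those, so a share without any dose effect lies below 33.3% by an unknown amount, and the rising genes decide nothing. The shares of replicates 2 and 3, each over its own set of genes, were 5.81% and 16.7% of falling genes and 25.7% and 17.5% of rising genes. A higher dose of virus may account for the falling genes but cannot be told apart from other differences of that pool, and no biological explanation was tested.

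The 16 genes listed on chromosome W took 120 CPM in RCAS(A)-Wnt9a replicate 3 and 155 to 178 CPM in the other libraries. The 848 genes listed on chromosome Z took 41350 CPM in RCAS(A)-Wnt9a replicate 3 and 38140 to 40090 CPM in the others. The cause was not tested.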
